A study of Zea mays with 2 samples.

How the data were processed

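RNA from endosperm at 15 days after pollination was analysed in 2 samples, 1 of wild type and 1 of the opaque2 mutant, and the genotype of each was taken from its labels. Per the labels, RNA was extracted with Trizol, cleaned up with a column kit and treated with DNase I, and libraries were made by standard Illumina protocols. The authors deposited FPKM values, per the file headers, at 1 value per locus and genotype. Per the submitters' processing notes, Bowtie 0.12.2 was used. Its role, the program that estimated FPKM, the genome build and the annotation are not given in the sources used here. The values are not whole numbers and carry no counts, so depth is unknown and no counting interval of a level can be given. The design text names triplicates, and how they relate to the 1 value per locus is not given in the sources used here.

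Both tables listed the same loci in the same order, and no locus was at 0 in both. Starts in the tables count from 0, as tested on organelle loci: 48 mitochondrial starts equal a start of the reference table after adding 1, and 0 without it. Positions are therefore given with 1 added to the start. Of the loci, 9394 share 4442 positions with other loci, so a position is the span of overlapping models and not the length of a transcript. A value of exactly 0 can also be a failed estimate, so no fold is given for a single locus listed at 0 in a library, although counts of changed loci include such loci.

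From these values the log2 ratio of opaque2 over wild type was computed with a pseudocount of 1, on the scale as deposited. A locus counted as changed when it differed at least 2-fold and reached 5 FPKM in the higher library. This rule of size, the floor and the alternatives not marked as added were fixed before the data were examined. With 1 library per genotype no test across genes was made. Shares of loci carry exact Clopper-Pearson 95% intervals. Chromosomes, 5-Mb windows of at least 15 loci and runs of at least 3 consecutive loci past the floor were described against 10000 shuffles of the calls within 20 bins of mean level. Medians of organelle loci were set against 10000 random lists of nuclear loci matched on mean level in 20 bins. These positional summaries were chosen after the data were seen. The rule was also run on simulated values for the opaque2 and wild type comparison, with 200 loci changed 4-fold among 15574 past the floor. It recovered 200 and called 4 others. A 4-fold change lies beyond the 2-fold rule, so the recovery was largely fixed by the design. Without replicates the noise of the real libraries is unknown, so the 4 others do not estimate false calls among the changed loci.

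Gene names came from the RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0, through exact matches of start and end in the organelle genomes. This assumes that the organelle sequences are those of the table. None of the 43974 nuclear loci matched in this way, that is 0, and positions were not converted. A matched chloroplast gene is not reported here. The rule for named genes, fixed before the data were examined, was the opaque2 gene, members of fixed gene lists with the largest ratios, the 12 highest and 12 lowest ratios among genes with a name, and the 5 loci of highest level. Of these, the last part was applied to nuclear loci, and the 2 highest and 2 lowest ratios are given by position. For these, the conditions of 300 bp or more and of a value above 0 in both libraries were added after the values were seen. The 21 gene lists, the share of zein genes and the level of the opaque2 gene were not analysed here for want of names. All named organelle genes and regions were chosen after the values were seen.

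Alternatives were equal totals of all loci, centring on the median ratio, pseudocounts of 0.1 and 5, floors of 1 and 20 FPKM and no floor, and changes of 1.5-fold and 4-fold. Added after the data were seen were loci above 0 in both libraries, loci of 300 bp or more, both together, equal totals without the 6 highest loci, and the chromosome 4 block without its highest locus, runs with the loci of each position summed, and sums of runs over loci above 0 in both libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.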

Results

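The series compared maize endosperm, the starch and storage protein tissue of the kernel, from wild type plants and from the opaque2 mutant at 15 days after pollination (DAP). Opaque2 is a transcription factor of the bZIP family that acts in the endosperm, and its best known targets are genes of zeins, the main storage proteins of the grain. RNA was sequenced, and 1 value per locus was analysed for each genotype, in FPKM, fragments scaled by the length of the transcript and the size of the library. The design text speaks of triplicates, but whether the values pool or average several libraries is not given in the sources used here. No difference below therefore has a replicate check, and no p-value is given. The depth of each library is unknown, since the values carry no counts. Both genotypes were listed for the same 44119 loci, given by position alone at 39167 distinct positions. All but 30 of these loci lay on the 10 chromosomes and the 2 organelle genomes. The median level was 1.59 FPKM in opaque2 and 1.62 FPKM in wild type, and the summed values were 2138613 and 2137410 FPKM.

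The comparison of opaque2 with wild type asks which transcripts differ when this regulator is mutated. Loci that differed at least 2-fold were found in both directions in about equal number. Of 15833 loci with 5 FPKM or more in the higher library, 644 were higher and 608 were lower in opaque2, together 7.91% of them. The median log2 ratio of opaque2 over wild type was −0.04, with quartiles at −0.26 and 0.20, and 82.6% of the loci lay within 1.5-fold. Beyond 4-fold, 322 loci were higher and 189 lower. Of the higher loci, 210 were listed at 0 in wild type, and of the lower loci, 87 were listed at 0 in opaque2. Among loci above 0 in both libraries the balance at 2-fold turned, with 434 higher and 521 lower, and at 4-fold 112 were higher and 102 lower. Short loci weighed heavily in these counts: 51.3% of the 626 loci shorter than 300 bp passed the rule, against 6.12% of the 15207 longer ones.

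**Figure D1:**
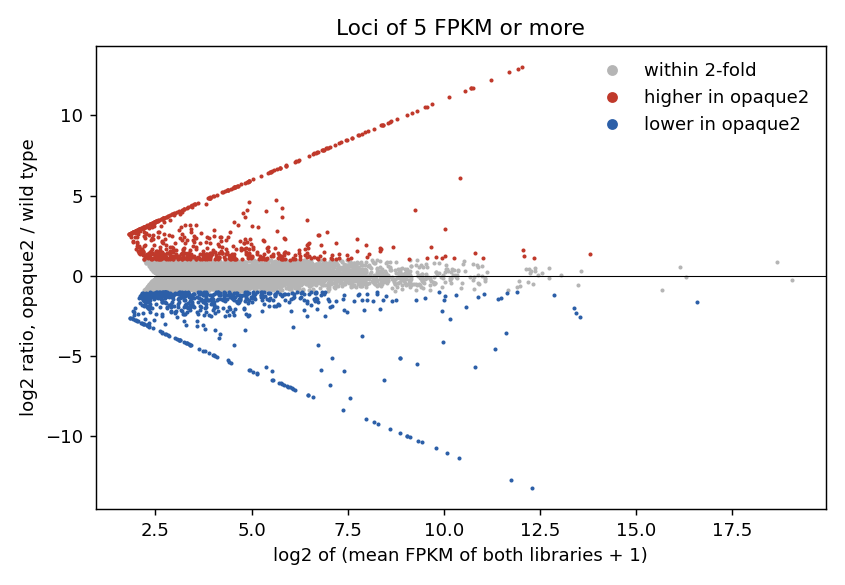
Log2 ratio of opaque2 over wild type for each of 15833 loci (y axis) against the log2 of the mean FPKM of both libraries plus 1 (x axis), with the 644 higher loci in red, the 608 lower loci in blue and the others in grey. The 2 straight edges are loci listed at 0 in 1 library, whose ratio is set by the pseudocount.

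Among loci of 300 bp or more that were above 0 in both libraries and reached 20 FPKM, the lowest ratio was on chromosome 5 at 107924664 to 107925342, with 0.824 FPKM in opaque2 and 374 FPKM in wild type (log2 ratio −7.68). The next was on chromosome 7 at 10793341 to 10796233, with 1.304 FPKM in opaque2 and 259 FPKM in wild type (log2 ratio −6.82). The highest ratio was on chromosome 7 at 14459963 to 14466085, with 2720 FPKM in opaque2 and 39.7 FPKM in wild type (log2 ratio 6.06). The second highest was on chromosome 1 at 287062939 to 287065014, with 94.1 FPKM in opaque2 and 2.67 FPKM in wild type (log2 ratio 4.70). With a pseudocount of 5 in place of 1, these 4 log2 ratios were −6.02, −5.39, 5.93 and 3.69. The files do not pair nuclear loci with gene names, and their genome build is not given in the sources used here. For this reason the opaque2 gene itself, which the reference table places on chromosome 7, and the zein genes were not analysed by name.

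The longest run of neighbouring loci that changed the same way was a block on chromosome 4 where every locus that reached 5 FPKM was lower in opaque2. It ran from 5075029 to 5172399, over 97.4 kb, with 14 loci at 8 distinct positions. Their summed level was 648 FPKM in opaque2 and 13761 FPKM in wild type, 21.2-fold lower (log2 ratio −4.41). Single loci of the block ranged from 7.14 to 5859 FPKM in wild type, and 11 of the 14 lay above 47.5 FPKM, the 95th percentile of all loci in that library. Of these loci, 3 were listed at 0 in opaque2, and the log2 ratios of the other 11 ran from −6.54 to −3.61. Loci at one position overlap and may be near copies, so the split of reads among them is uncertain. A single locus held 480 of the summed FPKM in opaque2 and 5859 in wild type, and without it the sums were 168 and 7902 FPKM, 47.0-fold lower in opaque2 (log2 ratio −5.55). The next 10 loci of 5 FPKM or more, at 5240153 to 5466543, had log2 ratios between −0.32 and 0.51, and none of them passed the rule. Farther on, 10 loci at 5490429 to 5591069 held 10680 FPKM in opaque2 and 14570 FPKM in wild type in sum (log2 ratio −0.45), with 4 loci lower and 1 higher by the rule. Both regions were picked after their values were seen.

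**Figure D2:**
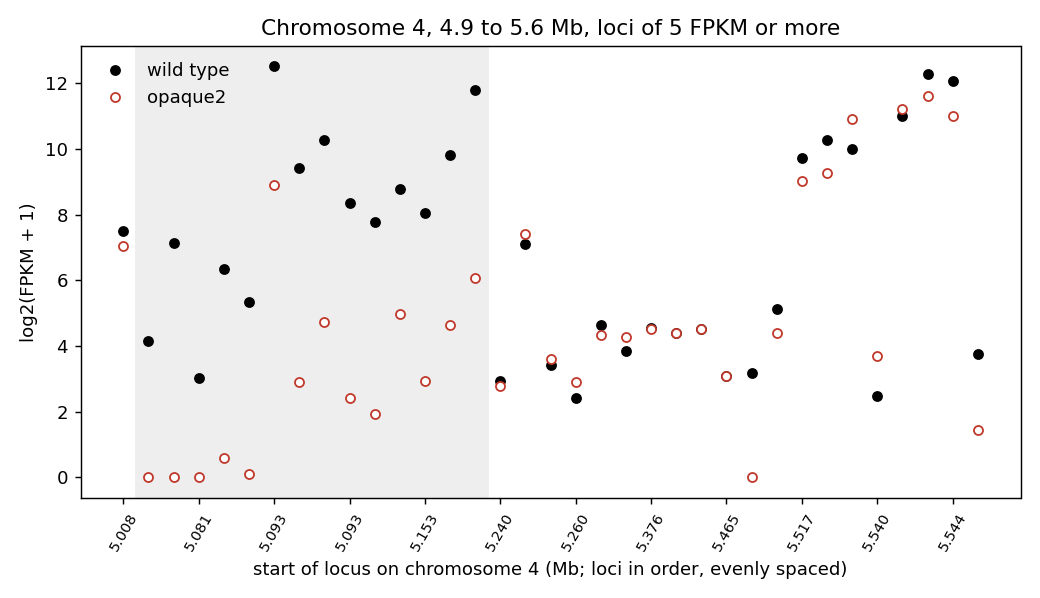
Level of each locus of 5 FPKM or more at 4.9 to 5.6 Mb of chromosome 4 as log2 of FPKM plus 1 (y axis), in order of position and evenly spaced (x axis, start in Mb), for wild type (filled) and opaque2 (open). The shaded block holds the 14 loci that were all lower in opaque2.

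Changed loci were more frequent on chromosome 7, which carries the opaque2 gene in the reference table, than elsewhere. By the rule of size 76 loci of chromosome 7 were higher and 75 lower, 11.96% of its 1263 loci (95% Clopper-Pearson interval 10.2% to 13.9%, which treats loci as independent). On the other 9 chromosomes together the share was 7.59%, and chromosome 1 came next to chromosome 7 with 9.58%. When the calls were shuffled 10000 times among loci of like mean level, chromosome 7 had a median share of 8.16% and at most 11.2%, a description of these libraries and not a test of the genotypes. In the stretch at 5 to 20 Mb, chosen after its values were seen, 28 loci were higher and 21 lower of 176 (27.8%). In the rest of chromosome 7 the share was 9.38%. The 5-Mb windows just beyond the stretch, at 20 to 25 Mb and 25 to 30 Mb, had 18.5% (5 of 27 loci) and 23.1% (6 of 26 loci). The stretch thus had no clear edge at 20 Mb. On its other side, at 0 to 5 Mb, 0 of 43 loci changed.

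In windows of 5 Mb with at least 15 loci, the 3 highest shares as reported were 44.8% on chromosome 3 at 20 to 25 Mb (13 of 29 loci), 42.1% on chromosome 7 at 10 to 15 Mb (24 of 57 loci) and 36.2% on chromosome 4 at 5 to 10 Mb (21 of 58 loci). The chromosome 3 window had 9 loci higher and 4 lower, and the chromosome 7 window had 13 higher and 11 lower. High shares on chromosome 3 also extended to the windows on either side. They were 25.5% at 15 to 20 Mb (12 of 47 loci) and 22.7% at 25 to 30 Mb (5 of 22 loci). In the chromosome 4 window 18 loci were lower and 3 higher, the block above among them. Further windows with high shares were on chromosome 7 at 95 to 100 Mb (33.3%, 8 of 24 loci), on chromosome 9 at 105 to 110 Mb (30.3%, 10 of 33 loci) and on chromosome 7 at 70 to 75 Mb (29.4%, 5 of 17 loci). In the shuffled calls the windows named first on chromosomes 3, 7 and 4 reached at most 31.0%, 28.1% and 25.9%, and the highest of all 354 windows reached a median of 26.7% and at most 47.4%. Among the 116 windows of 50 or more loci, the size of those on chromosomes 7 and 4, shuffled calls reached at most 31.4%. Since the 3 windows named first were picked as high, their own shuffled values only describe them. The order of those 3 depended on the setting: at 4-fold the shares were 17.2%, 24.6% and 29.3%, and without a floor 19.4%, 24.2% and 20.6%.

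**Figure D3:**
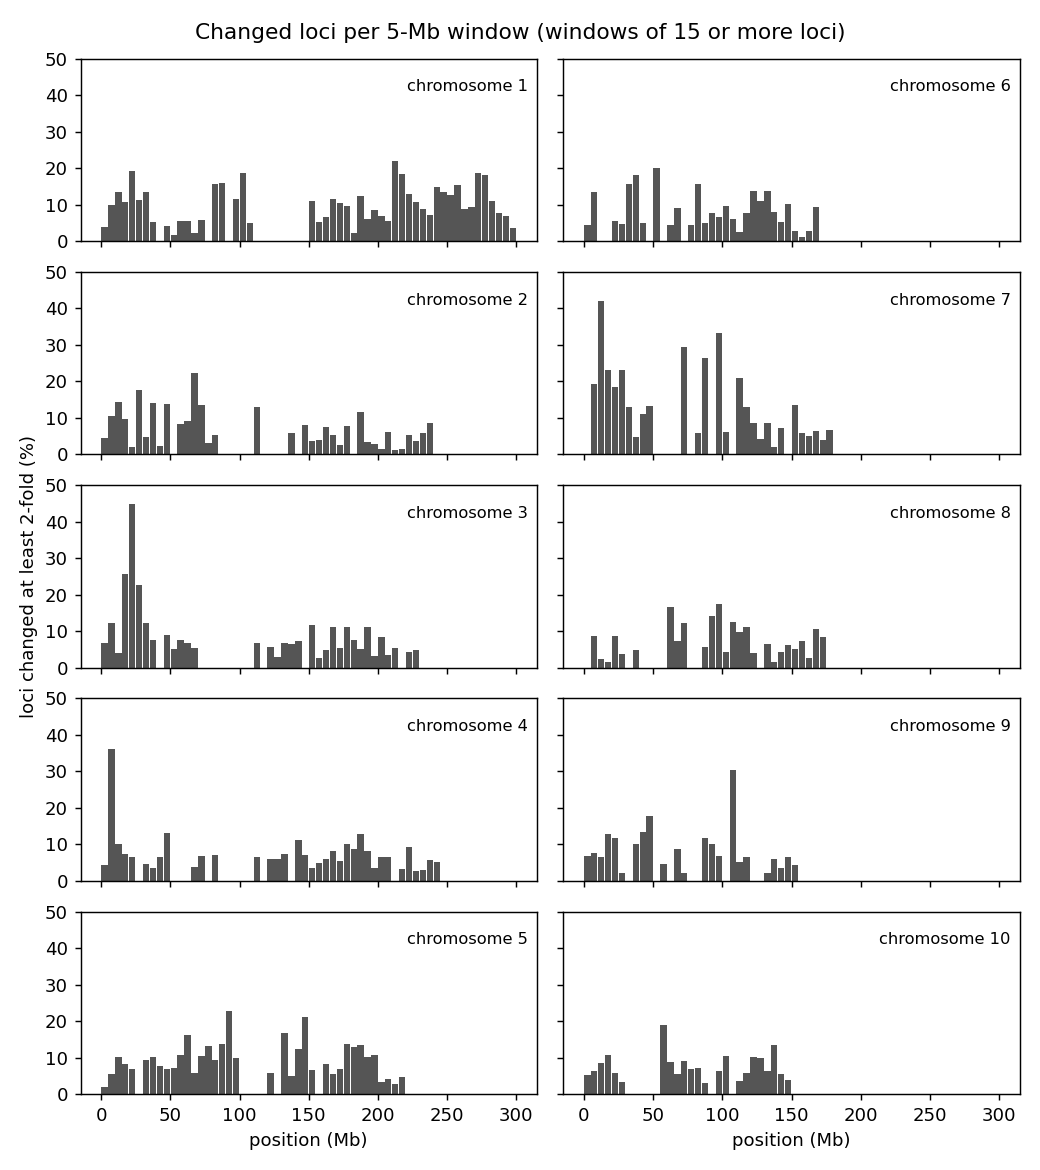
Share of loci that differed at least 2-fold between opaque2 and wild type (y axis, percent of loci of 5 FPKM or more) in 5-Mb windows along the 10 chromosomes (x axis, Mb), for windows of 15 or more loci. The tallest bars are on chromosomes 3, 7 and 4, at 44.8%, 42.1% and 36.2%.

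Runs of neighbouring loci that changed the same way were also frequent on chromosome 7. Of 14 runs of 3 or more consecutive loci that changed the same way, 10 were on chromosome 7, and shuffled calls gave a median of 2 runs and at most 12 in the whole genome. With the loci of each position summed, there were 10 runs, 6 of them on chromosome 7, and the longest was the chromosome 4 block with 8 positions, against at most 5 in shuffled calls. The shuffled calls then gave up to 10 runs, as many as observed. The shuffles moved calls over the whole genome. They cannot show whether chromosome 7 had more runs than its higher share of changed loci would give. All 6 loci from 15469931 to 16099019 were higher in opaque2, but 2 of them were listed at 0 in wild type, among them a locus of 96 bp with 1466 FPKM. The other 4 summed to 104 FPKM in opaque2 and 25.8 FPKM in wild type. All 6 loci from 12618639 to 12744826 were higher as well, and 1 of them, of 113 bp, was listed at 0 in wild type. The other 5 summed to 231 FPKM in opaque2 and 49.6 FPKM in wild type. In the other direction, 3 loci from 11433783 to 11439021 were all listed at 0 in opaque2 and summed to 52.4 FPKM in wild type. A group of 6 loci of nearly equal length, 722 to 726 bp, at 18744943 to 18867189 was split. Its first 3 members were lower in opaque2, with 134 against 2852 FPKM in sum, while its last member was higher, with 6445 against 2091 FPKM. The whole group held 12071 FPKM in opaque2 and 9007 FPKM in wild type (log2 ratio 0.42). Members of such a group may share reads, so their single values are uncertain.

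**Figure D4:**
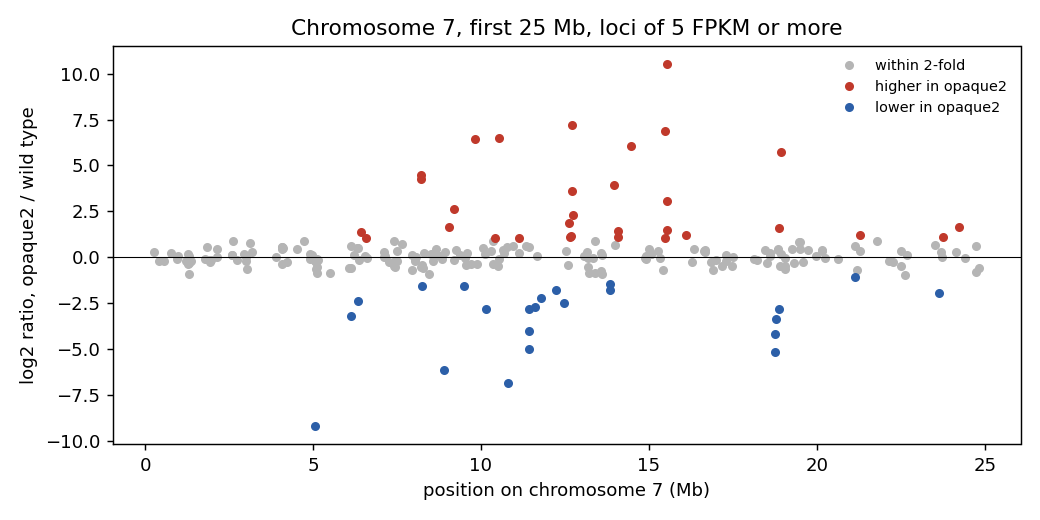
Log2 ratio of opaque2 over wild type (y axis) of each locus of 5 FPKM or more in the first 25 Mb of chromosome 7 (x axis, Mb), with higher loci in red, lower loci in blue and the others in grey. Between 5 and 20 Mb, 28 loci were higher and 21 lower, and ratios of loci listed at 0 in 1 library are set by the pseudocount.

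Organelle transcripts were compared as a group outside the nuclear genome. Start and end matched a gene of the reference table exactly for 33 of 84 mitochondrial loci and 6 of 31 chloroplast loci, and names given here come from those matches. None of the 25 named mitochondrial genes past 5 FPKM changed 2-fold, and their log2 ratios ran from −0.55 to 0.60. For subunits of respiratory complex I, nad4 had 1592 FPKM in opaque2 and 1677 FPKM in wild type, nad3 had 707 and 663 FPKM, nad6 had 662 and 728 FPKM, and nad9 had 702 and 1029 FPKM. The ATP synthase gene atp6 had 627 FPKM in opaque2 and 749 FPKM in wild type. Of the ribosomal protein genes, rps12 had 1107 and 1210 FPKM and rps4 had 81.9 and 80.4 FPKM. The highest named mitochondrial locus, orf147-b, had 5809 FPKM in opaque2 and 4821 FPKM in wild type. The median log2 ratio of all 64 mitochondrial loci past 5 FPKM was −0.04, at percentile 24.4 of 10000 random lists of nuclear loci of like level. By the rule 2 of them were lower, both listed at 0 in opaque2.

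The chloroplast loci had a median slightly below 0, and none of them passed the rule. Their median log2 ratio was −0.18 over 24 loci, 20 of them below 0, at percentile 1.86 of the random lists. Loci of an organelle genome may vary together, unlike nuclear loci drawn at random. The percentiles of both organelles therefore describe these libraries and are no test. The ribosomal protein gene rpl14 had 197 FPKM in opaque2 and 255 FPKM in wild type. The translation initiation factor gene infA had 44.5 FPKM in opaque2 and 76.7 FPKM in wild type (log2 ratio −0.77). For the plastid RNA polymerase, rpoB had 5.51 and 6.40 FPKM, and rpoC1 had 14.3 and 16.6 FPKM. The gene of a further subunit, rpoC2, was below 1 FPKM in both libraries.

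**Figure D5:**
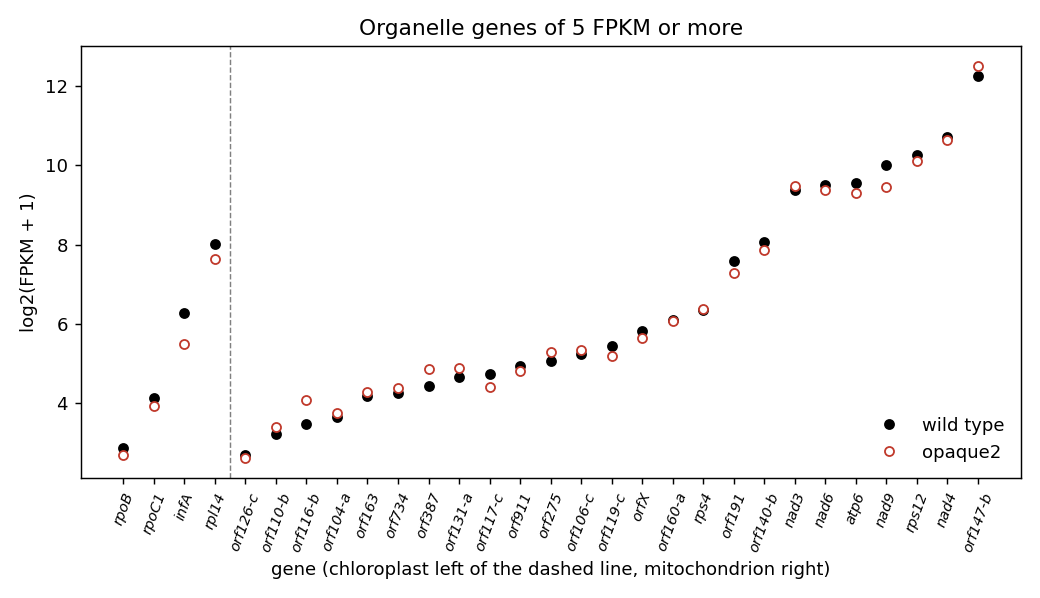
Level of named organelle genes of 5 FPKM or more as log2 of FPKM plus 1 (y axis) in wild type (filled) and opaque2 (open), with 4 chloroplast genes left of the dashed line and 25 mitochondrial genes right of it, each by rising wild type level. No gene shown differed 2-fold, and infA had the lowest log2 ratio, −0.77.

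A few short loci took most of the summed values. The 6 loci of highest mean level, none longer than 402 bp, held 60.3% of the sum in opaque2 and 59.0% in wild type. The highest, on chromosome 9 at 20459075 to 20459382, had 502122 FPKM in opaque2 and 598365 FPKM in wild type (log2 ratio −0.25). The next, on chromosome 8 at 19493019 to 19493185, had 538900 FPKM in opaque2 and 300880 FPKM in wild type (log2 ratio 0.84). The third, on chromosome 1, was lower in opaque2, with 48024 FPKM against 148797 FPKM (log2 ratio −1.63). The last 2 of the 5 highest, on chromosomes 1 and 8, had log2 ratios of −0.12 and 0.52. FPKM divides by length, and at so short a length a small error in the effective length moves the value strongly.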

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

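The share of changed loci on chromosome 7 stayed 1.44 to 1.77 times that of the other 9 chromosomes in every alternative run, against 1.58 as reported. At 5 to 20 Mb of chromosome 7 the share changed was 17.0% to 41.5%. Runs of neighbouring loci numbered 6 to 54, with 4 to 17 on chromosome 7. Most runs lay elsewhere at 1.5-fold, with 11 of 54 on chromosome 7. The same held with a floor of 1 FPKM (17 of 47) and without a floor (10 of 27). With a floor of 20 FPKM it was 5 of 10, and under the other settings most runs were on chromosome 7. At 1.5-fold, the windows on chromosomes 3 and 7 had 65.5% and 57.9% of loci changed. In the chromosome 4 block 11 to 14 loci were lower in opaque2 across the alternatives. The counts of 11 and 12 came from filters that removed loci, and those of the 14 that were kept stayed lower. With log2 ratios of −3.02 or lower as reported, they passed each fold rule by construction. The log2 ratio of its sums lay between −5.55 and −4.36, and the value of −5.55 came from leaving out its highest locus, an alternative chosen after seeing the data. The counts of changed loci followed the rule. With a pseudocount of 5, which pulls ratios toward 0 by construction, 823 loci changed and 378 were lower. With a floor of 1 FPKM, 2226 changed, 1271 higher and 955 lower, and without a floor the counts were 2226, 1271 and 955 again, as a 2-fold ratio with the pseudocount needs 1 FPKM. With a floor of 20 FPKM, 611 changed, 308 higher and 303 lower. At 4-fold, 511 changed, 322 higher and 189 lower, and at 1.5-fold, 2761 changed, 1349 higher and 1412 lower. Loci of 300 bp or more and above 0 in both libraries, a filter chosen after seeing the data, gave 828 changed and 401 higher from fewer loci. Equal totals and centring kept each count within 1.5 times, but the balance of directions moved. Centring gave 678 higher and 579 lower, and equal totals without the 6 highest loci gave 695 higher and 577 lower. For ratios and medians, which have no replicates, a move of over 1.5-fold was taken as a change. The chloroplast median stayed between −0.21 and −0.13. The mitochondrial median lay between −0.13 and 0.01, and its sign turned with equal totals without the 6 highest loci. At 1.5-fold, 2 named organelle genes passed. The 2 lowest and 2 highest ratios kept their direction in each alternative, but 3 of them moved by over 1.5-fold with the pseudocount. At 0.1 and 5, the chromosome 5 locus had −8.66 and −6.02 and the lower chromosome 7 locus −7.53 and −5.39, and the chromosome 1 locus had 3.69 at 5. Other loci given by position were not run one by one. Gene list medians, the zein share, scaling without zeins and the level of the opaque2 gene were not run, as names were lacking, nor were the alternatives for counts or replicates. No paired analysis was possible because each genotype has 1 column. Depth is unknown, so what it limits at low levels was not measured.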

Other observations

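The tests of the low-level and of the shared-read explanation on chromosome 7 were set before their values were seen, and the other tests here were chosen after the result was seen.

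Loci listed at 0 were unevenly split between the genotypes. In wild type 4885 loci (11.1%) were listed at 0, and in opaque2 1384 loci (3.14%), a ratio of 3.53. Among loci of 0.01 to 0.05 FPKM in opaque2, 46.3% were listed at 0 in wild type, while in the reverse direction it was 9.14%. Among loci of 20 FPKM or more, 108 were at 0 in wild type alone and 46 in opaque2 alone.

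A lower depth of the wild type library may produce more values of 0 at low levels. The lowest values above 0 of FPKM times span, where 1 fragment weighs most, were 1.14 times higher in wild type (95% bootstrap interval 1.09 to 1.17). A depth difference behind the whole excess was taken to need a ratio of at least 2.5, and the measured ratio was well below that. That limit of 2.5 was set by choice and not derived from the data, and span is not the length of a transcript. Values so near the lower limit of detection also decide little without counts. Lower depth therefore stays open, as a partial or as the whole source. Most of the excess at 20 FPKM or more sat in loci shorter than 300 bp, where few fragments give a high value. Among longer loci 24 were at 0 in wild type alone and 22 in opaque2 alone, a ratio of 1.09 (95% interval 0.586 to 2.04). No clear excess was thus seen among longer loci of 20 FPKM or more, and the wide interval cannot decide on depth. At 5 FPKM or more, 62 longer loci were at 0 in wild type alone and 41 in opaque2 alone. Failed estimates at expressed loci cover a small part, since 4.30% of the loci at 0 in wild type had 5 FPKM or more in opaque2. No biological explanation was tested.

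The excess of changed loci on chromosome 7 was not a matter of low, short or zero-listed loci alone. Among loci of 20 FPKM or more, of 300 bp or more and above 0 in both libraries, the share on chromosome 7 was 1.72 times that of the other 9 (95% interval 1.299 to 2.23). With each run of neighbouring calls and each shared position counted once, it was 1.42 times (95% interval 1.17 to 1.70). This argues against neighbours that share reads as the whole source. Both intervals reflect loci and not replicates, as each genotype has 1 library. The first also counts neighbours in runs and loci of shared positions separately. A candidate explanation is a chromosome segment of the mutant's donor line around the opaque2 gene, with alleles of other expression or with sequence that differs from the reference. Only the chromosome of that gene was taken from the reference table. Whether the gene lies at 5 to 20 Mb in these positions was not tested. That stretch was picked for its high share, so a lower share in the rest of chromosome 7 was partly fixed by the choice. Outside 5 to 20 Mb the share was 1.24 times that of the other chromosomes. At 9.38% it lay just under 9.48%, the upper end of the 95% range of the shuffled calls. The windows at 20 to 25 Mb and 25 to 30 Mb, with 18.5% and 23.1% of loci changed, lie in that part. So do those at 70 to 75 Mb and 95 to 100 Mb, with 29.4% and 33.3%. Whether such a segment exists cannot be told apart from effects of the mutation here, since the parent lines and their genotypes are not given in the sources used here.

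For the chromosome 4 block, reads that move between near copies inside it would lower some loci and raise others. All 14 loci were lower in opaque2, and their sum was 21.2-fold higher in wild type. The block was picked as a run of lower loci, so these values restate the choice and are no separate test of such moves. FPKM divides by length, so moves between loci of unlike length would also change the sum. A move of reads to the nearby group at 5490429 to 5591069 would raise that group, and its opaque2 sum was 0.733 times the wild type sum. Copies elsewhere in the genome and sequence variants of the mutant line were not tested. A hypothesis is that the block is an array of storage protein genes under opaque2 control, which may be expected among the most abundant transcripts of endosperm. In the wild type library 11 of the 14 loci were above the 95th percentile of all loci. That was partly fixed by the choice, since each had to reach 5 FPKM in wild type, where the median of all loci was 1.62 FPKM. Of the 14 loci, 8 also share a position with others. The loci have no names here, so an array of other abundant genes cannot be told apart from one of storage protein genes.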
